A study of Mus musculus with 4 samples.

How the data were processed

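Gene expression was measured by RNA sequencing in mice of the BL6/C57 strain, young adult males, whose left sciatic and femoral nerves had been cut 7 days earlier. RNA came from dorsal root ganglia (DRG, which hold the cell bodies of the sensory neurons) at lumbar levels 4 to 6, and from the dorsal part of the lumbar spinal cord, where those neurons project. Each tissue was taken on the side of the cut (ipsilateral) and on the opposite side (contralateral). This gives 4 libraries in 4 groups, 1 library per group. Whether a library pools several animals is not given in the sources used here. The contralateral side comes from operated mice, so it is an internal reference and not uninjured tissue.

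Per the labels' protocols, total RNA was purified with the QIAGEN RNeasy Mini Kit and libraries were made with the Epicentre ScriptSeq mRNA-Seq kit. Per the submitters' processing notes, TopHat 1.4.0 and Cuffdiff 1.3.0 were used with the mouse genome build mm9. The gene annotation, filters and strand setting were not given in the sources used here. Each tissue has its own table, and each table lists 21883 features under unique symbols. Per the file headers, the authors' deposited tables give each library's level in FPKM (fragments per kilobase of transcript, scaled to the mapped fragments). They also give the authors' p-values and q-values, a log2 fold change, a test statistic and a test status for each feature. Because FPKM divides by length, a few fragments on a very short feature give a high value. The Cuffdiff p-values compare 1 library with 1 library, so they describe those libraries and not the conditions. The 2 tables were normalised separately, so ratios were taken within a table, and levels set across tissues are approximate.

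The main measure computed from the deposited FPKM was the log2 of (ipsilateral + 1) over (contralateral + 1). The pseudocount of 1 FPKM understates differences of low genes. A gene counted as measured at 1 FPKM or more in either library, which held for 13137 features in DRG and 13351 in dorsal cord. A gene counted as 2-fold higher or lower at a log2 ratio of at least 1 or at most -1. Plain folds, where given, are ratios of the deposited FPKM without the pseudocount. Except for BC096441 in cord, no single-gene ratio is given against a library listed at 0, because such a value can be a failed estimate. With 1 library per group no difference has a replicate check, and no p-value was computed. No other columns of per-sample values were left out (0).

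Depth is not given, but it can be compared between the libraries of a tissue. The authors' test statistic equals the log2 fold change divided by a standard error, and the deposited p-values match a two-sided normal test of it for 100% of the genes with both libraries above 0. Genes whose standard error implies a single read in each library show what 1 read is worth. In DRG, 50 of 52 such genes had a log2 ratio that rounds to -0.65, so 1 read was worth 0.639 times as much FPKM ipsilaterally as contralaterally. In dorsal cord, 20 of 20 had one that rounds to 0.43, so 1 read was worth 1.35 times as much ipsilaterally. The absolute read numbers stay unknown. The standard error implied by the authors' deposited table had a median of 0.44 in DRG and 0.57 in cord for genes with a mean of 1 to 3 FPKM. It levelled off at 0.26 in DRG and 0.25 in cord from 30 FPKM. Where an interval is given for a fold, it is the 95% interval from that standard error and leaves out variation between animals.

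Before the data were examined, 36 gene lists (cell type markers, channels, injury genes and pathways) were fixed, along with 15 index genes around Csf1, its receptor and the microglial adaptor DAP12. For each list with at least 3 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart below the 2.5th or above the 97.5th percentile. This describes these libraries and is not a test of the conditions. Lists share members, so they are not independent. Genes named in the text are the index genes, the 10 largest and 10 smallest log2 ratios per tissue, up to 4 members per list and tissue with the largest absolute log2 ratio, and the 10 strongest genes higher or lower in both tissues. Because small RNA features filled most of the largest ratios, the same ranking among genes called significant in the authors' deposited tables was added after seeing the data. Other members named for contrast were chosen after their values were seen.

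The alternatives fixed beforehand were pseudocounts of 0.1 and 3 FPKM, no filter or a filter at 5 FPKM, median and upper-quartile rescaling, the authors' test status, the authors' significance calls (q up to 0.05), and summed rows of a symbol. A correction for GC content (the median of each of 20 GC classes subtracted), a count without small RNA features, and a count that needs both the fold and the authors' call were added after seeing the data. GC content was taken from the transcripts of GENCODE M21 on GRCm38, matched by symbol for 99.0% of measured DRG genes and 98.9% of measured cord genes, and no coordinate was taken from that build. Coordinates are those of the deposited tables on mm9, counted from 1. The calculation was tested on simulated data with 200 changed genes per tissue. The simulation held only genes with a mean of at least 3 FPKM, detected in both libraries and tested by the authors' software. Its noise came only from the standard error implied by the authors' deposited table. Its rates therefore do not cover lower genes, genes missing from a library or variation between animals, and are not error rates of the counts below. In simulated DRG libraries of 10385 genes, 4-fold and 8-fold changes were called in 100% of cases, and 0.15% of unchanged genes were called. In simulated cord libraries of 10701 genes, 98.0% of 4-fold increases and 96.0% of 4-fold decreases were called, and 0.44% of unchanged genes were called. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Some listed symbols were not analysed here, and the values of some others are not reported here.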

Results

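The data comprise 4 RNA libraries from mice examined 7 days after the left sciatic and femoral nerves were cut. They cover ipsilateral and contralateral lumbar DRG, and ipsilateral and contralateral lumbar dorsal spinal cord, with 1 library each. The design addresses which transcripts differ on the injured side, in the ganglia that hold the cut neurons and in the cord segment that receives their input. None of the differences below has a replicate check. The summed FPKM of the libraries was close, at 431795 contralateral and 442298 ipsilateral in DRG, and 425636 and 442196 in dorsal cord. The median log2 ratio over measured genes was 0.05 in DRG and 0.02 in cord.

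In the ipsilateral DRG, genes of nerve injury and regeneration had the largest median log2 ratio of the fixed lists. Of the 26 measured genes of this list, 20 were at least 2-fold higher and 0 were 2-fold lower, with a median log2 ratio of 2.23, above all 10000 matched random lists (percentile 100). Sprr1a, a small proline-rich protein linked to axon outgrowth, stood at 782 FPKM ipsilaterally and 6.25 contralaterally, a log2 ratio of 6.76. The neuropeptide gene Npy followed at 373 against 6.26 FPKM (5.69), and Atf3, a transcription factor induced by axon injury, at 389 against 12.6 (4.85). The orphan receptor gene Gpr151 was at 48.2 against 0.91 FPKM (4.69).

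Several neuropeptide genes were among the highest. Gal, encoding galanin, was at 232 FPKM ipsilaterally and 8.47 contralaterally (log2 ratio 4.62). Nts, encoding neurotensin, was at 245 against 10.1 FPKM (4.47), and Crh, encoding corticotropin-releasing hormone, at 11.7 against 0.34 (3.25). Cckbr, a cholecystokinin receptor gene, was at 32.9 against 0.80 FPKM (4.23). Gap43, a growth cone protein gene, was at 924 against 273 FPKM (1.76) and the semaphorin gene Sema6a at 64.7 against 6.45 (3.14). Bdnf, a member of the same list, was at 8.30 FPKM ipsilaterally and 10.3 contralaterally (-0.28). The 20 measured members that the authors' deposited table calls significant were all higher ipsilaterally. For Atf3 (mm9 chromosome 1, 192994176 to 193007212) the 31.0-fold difference had an interval of 20.7 to 46.3 from the standard error implied by the authors' deposited table. For Sprr1a (chromosome 3, 92287876 to 92289803) the 125-fold difference had an interval of 73.2 to 214 from the same source, the authors' deposited table.

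Csf1, which encodes the growth factor of macrophages and microglia, was 5.73-fold higher in ipsilateral DRG, at 63.1 against 11 FPKM (log2 ratio 2.42). Its interval from the authors' deposited table was 4.54 to 7.23. The gene lies on mm9 chromosome 3 from 107543966 to 107563387. Il34, the other ligand of the same receptor, was at 14.4 against 10.9 FPKM (0.37), with an interval of the fold from 0.86 to 2.03 in the authors' deposited table. The receptor gene Csf1r (chromosome 18, 61265226 to 61290793) was at 19.8 against 4.51 FPKM (1.92). Tyrobp, which encodes the adaptor DAP12 (chromosome 7, 31198807 to 31202598), was at 37.0 against 16.4 FPKM (1.13). Its partner receptor gene Trem2 was at 2.81 against 0.086 FPKM (1.81).

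In all, 400 features were at least 2-fold higher and 103 at least 2-fold lower in ipsilateral DRG, so 79.5% of these features were higher. The authors' deposited table calls 649 features significantly higher and 266 significantly lower, a split of 70.9% higher. Of the 2-fold features, 337 higher and 63 lower ones are also called in the authors' deposited table. The counts depend on the treatment of low values, with 679 higher and 259 lower at a pseudocount of 0.1 FPKM and 204 and 44 at a pseudocount of 3 FPKM.

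Genes of sensory neuron function were lower in ipsilateral DRG. The nociceptor list, genes typical of neurons that sense painful stimuli, had a median of -0.47 over 32 genes (percentile 0), with 24 genes below 0, 5 at least 2-fold lower and 1 at least 2-fold higher. Htr3a, a serotonin-gated channel gene, was at 11.9 FPKM ipsilaterally and 45.0 contralaterally (-1.84). The itch receptor gene Mrgprx1 was at 5.69 against 17.2 FPKM (-1.44), and Oprd1, the delta opioid receptor gene, at 2.20 against 6.06 (-1.14). The other 8 genes were above 0, and the 1 past 2-fold was Gfra1, a co-receptor gene for GDNF, at 183 against 67.0 FPKM (1.44). Genes of large-diameter sensory neurons had a median of -0.55 over 19 genes (percentile 0), with 17 below 0 and 0 past 2-fold. Among them were the transcription factor gene Etv1 at 32.1 against 56.8 FPKM (-0.80) and the heavy neurofilament gene Nefh at 610 against 990 (-0.70).

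Ion channel and receptor genes were lower as groups. The potassium channel list had a median of -0.58 over 37 genes (percentile 0), with 33 genes below 0. The 3 members at least 2-fold lower included Kcng4 at 2.17 against 5.89 FPKM (-1.12) and Kcnmb1 at 3.96 against 9.09 (-1.02). The list of sodium, calcium and HCN channel genes had a median of -0.33 over 31 genes (percentile 0). Scn1a was at 21.1 against 41.4 FPKM (-0.94) and Scn10a, a channel of nociceptors, at 87.8 against 158 (-0.84). In the opposite direction, Cacna2d1, which encodes the calcium channel subunit bound by gabapentin, was at 177 against 55.4 FPKM (1.66). For Cacna2d1 the authors' deposited table marks the test as failed. The list of GABA, glycine and glutamate receptor genes had a median of -0.37 over 23 genes (percentile 0), with Gria4 at 20.3 against 40.6 FPKM (-0.97) and the glycine receptor gene Glra1 listed at 0 against 4.76. The motor neuron list, many of whose genes DRG neurons also express, had a median of -0.47 over 9 genes (percentile 0.02), with Ache at 14.3 against 29.5 FPKM (-1.0).

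Genes of myeloid cells were higher in ipsilateral DRG. Of 25 pan-myeloid genes, 15 were at least 2-fold higher and 0 were 2-fold lower, with a median of 1.06 (percentile 100). Emr1, the F4/80 gene of macrophages, was at 8.54 against 2.08 FPKM (1.63), and the Fc receptor gene Fcgr2b at 10.2 against 2.35 (1.74). The list of blood-derived macrophage genes, some of which resident macrophages also express, had a median of 1.07 over 14 genes (percentile 100). Of these, 8 were 2-fold higher, led by Ms4a7 at 10 against 1.49 FPKM (2.15) and Mrc1 at 14.7 against 3.51 (1.80). This list cannot tell blood-derived from resident cells. Microglia identity genes had a median of 1.03 over 11 genes, 6 of them 2-fold higher (percentile 100), with Fcrls at 12.1 against 1.41 FPKM (2.45). Of the 14 genes in the microglia list, 4 are also in another list, and in DRG it cannot tell microglia from other macrophages. The list of DAP12 and microglial activation genes had a median of 0.93 over 25 genes, 7 of them 2-fold higher (percentile 100). Complement genes had a median of 0.62 over 18 genes, 6 of them 2-fold higher (percentile 100), including C1qa at 24.9 against 7.82 FPKM (1.56).

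The other index genes were less uniform in DRG. Ctss, encoding the protease cathepsin S, was at 32.7 against 10.5 FPKM (1.54) and the fractalkine receptor gene Cx3cr1 at 6.35 against 1.93 (1.33). Itgam, encoding CD11b, was at 7.54 against 3.46 FPKM (0.94) and Aif1, encoding Iba1, at 10.6 against 6.14 (0.70). The transcription factor genes Irf8 at 2.17 against 1.98 FPKM (0.09) and Irf5 at 3.38 against 2.97 (0.14), and the ATP receptor gene P2rx4 at 14.4 against 13.3 (0.10), were close between sides. Hcst, which encodes the adaptor DAP10, stayed under 1 FPKM on both sides.

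The cytokine and chemokine list was higher and the interferon response list lower in ipsilateral DRG. The list of cytokine and chemokine genes had a median of 0.63 over 20 genes (percentile 100), with 17 above 0 and 3 below. Of its genes, 7 were at least 2-fold higher and 1 at least 2-fold lower (-1.26). Besides Csf1, the higher genes included the monocyte chemokine genes Ccl8 at 6.66 against 0.75 FPKM (2.13), Ccl12 at 7.63 against 1.38 (1.86) and Ccl7 at 4.50 against 0.51 (1.86). Interferon response genes had a median of -0.33 over 30 genes (percentile 0), with 28 genes below 0 and 0 past 2-fold, for example Cmpk2 at 11.7 against 21.5 FPKM (-0.82). Antigen presentation genes had a median of -0.24 over 18 genes (percentile 0.08), with Tap1 at 3.09 against 6.92 FPKM (-0.95), while the class II gene H2-Aa was at 34.8 against 20.5 (0.73). Neutrophil genes had a median of -0.23 over 8 genes (percentile 2.13), which passed 2.5 at a pseudocount of 3 FPKM (percentile 3.30) and at a filter of 5 FPKM (percentile 2.72).

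Schwann cell myelin genes had a median of 0.25 over 16 genes, all above 0 (percentile 98.9), and repair Schwann cell genes a median of 0.31 over 13 genes (percentile 99.3). Jun, a member of the repair list and the injury list, was at 88.5 against 41.8 FPKM (1.06). Satellite glia genes had a median of 0.05 over 14 genes (percentile 55.4), with the glutamine synthetase gene Glul at 323 against 179 FPKM (0.85). The reactive astrocyte list, whose genes other reactive cells share, had a median of 0.53 over 20 genes (percentile 100), with Ptx3 at 3.55 against 0.44 FPKM (1.66) and Cd109 at 4.79 against 1.01 (1.53). Proliferation genes had a median of 0.00 over 20 genes (percentile 20.9). Housekeeping genes had a median of 0.26 over 13 genes (percentile 98.8), with Gusb at 11.3 against 5.22 FPKM (0.98) and Gapdh at 72.5 against 53.5 (0.43). Over the 34 DRG lists with a percentile, 15 stood above and 9 below the matched lists, where lists of randomly drawn genes would put 1.70 outside. Members of a list can vary together between any libraries, so 1.70 is not the number to be met between sides that do not differ.

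**Figure D1:**
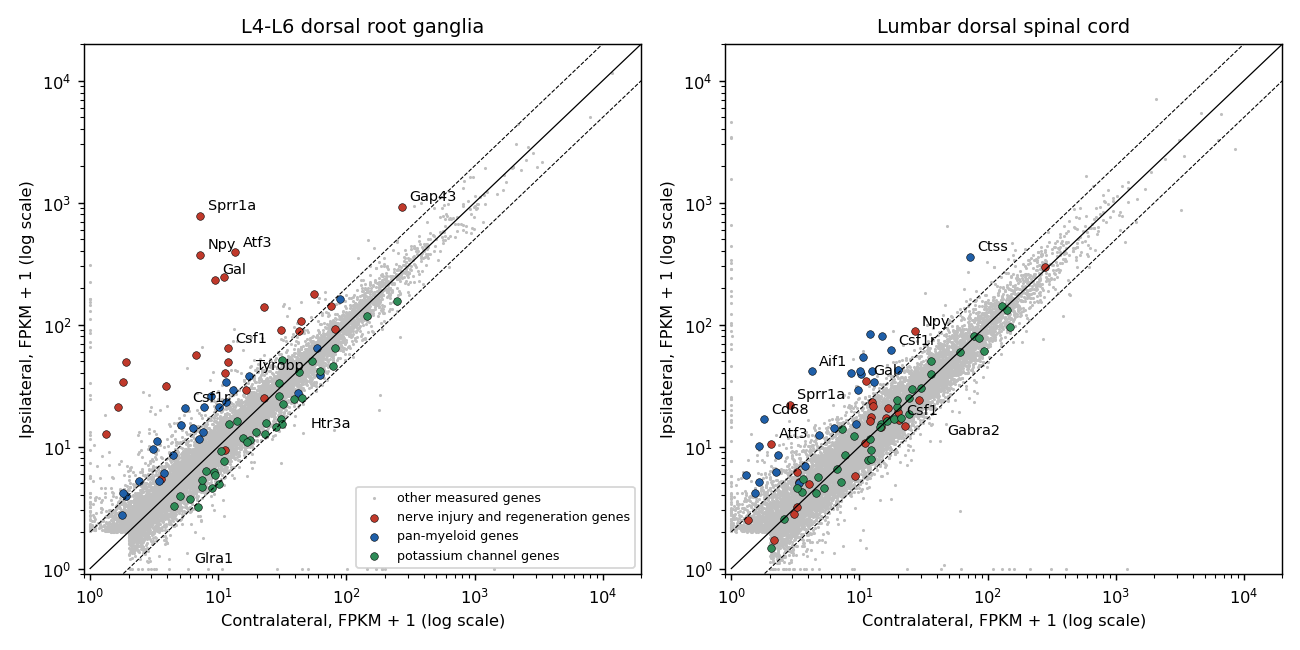
Ipsilateral against contralateral level of each measured gene, as FPKM + 1 on log axes, in DRG (left) and dorsal cord (right), with 1 library per side. Solid lines mark equal levels and dashed lines 2-fold differences, and coloured points are members of 3 gene lists, of which 20 of 26 injury genes lie above the upper dashed line in DRG and 22 of 25 pan-myeloid genes in cord.

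In the ipsilateral dorsal cord, genes of microglia and other myeloid cells had the largest median log2 ratios of the fixed lists. All 25 pan-myeloid genes were above 0 and 22 were at least 2-fold higher, with a median log2 ratio of 1.81 (percentile 100). Aif1, encoding Iba1, was at 40.5 FPKM ipsilaterally and 3.26 contralaterally (3.28), and the lysosomal gene Cd68 at 15.8 against 0.81 (3.22). The complement gene C1qb was at 83.3 against 11.1 FPKM (2.80) and Fcgr2b at 9.18 against 0.64 (2.63). Of 14 microglia identity genes, 12 were at least 2-fold higher, with a median of 1.43 (percentile 100), led by Olfml3 at 59.2 against 9.61 FPKM (2.5) and Fcrls at 15.5 against 2.95 (2.07).

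Most index genes of the microglial pathway followed this pattern. Irf5 and P2rx4 stayed under a log2 ratio of 1, and Csf1, Il34, Bdnf and Hcst were not higher. Csf1 was at 15.5 FPKM in ipsilateral and 19.4 in contralateral cord (-0.31), and the interval of the fold from the authors' deposited table was 0.58 to 1.09. Il34 was at 4.49 against 5.16 FPKM (-0.17). The receptor gene Csf1r was 3.65-fold higher, at 61.0 against 16.7 FPKM (1.81), with an interval of 2.58 to 5.16 from the authors' deposited table. Tyrobp was 4.09-fold higher, at 38 against 9.29 FPKM (1.92), with an interval of 2.07 to 8.09 from the authors' deposited table. Trem2 was at 14.3 against 6.24 FPKM (1.08), a difference the authors' deposited table does not call (q = 0.0957). Hcst was listed at 0 ipsilaterally and at 3.23 FPKM contralaterally, with q = 0.112 in the authors' deposited table.

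Itgam was at 39.2 against 7.55 FPKM (2.23), Ctss at 360 against 71.9 (2.31) and Cx3cr1 at 36.6 against 12.6 (1.46). Irf8, a transcription factor gene of microglia, was at 5.44 against 1.52 FPKM (1.36), and Irf5 at 3.20 against 1.43 (0.79). P2rx4 was at 6.29 against 4.42 FPKM (0.43) and Bdnf at 2.22 against 2.24 (-0.01). The authors' deposited table calls neither Irf5 (interval of the fold 1.03 to 4.91) nor P2rx4 (0.78 to 2.59). The list of DAP12 and microglial activation genes had a median of 1.05 over 24 genes (percentile 100), with 13 at least 2-fold higher and Hcst the 1 at least 2-fold lower. Only 3 of the 16 genes of the blood-derived macrophage list reached 1 FPKM in cord, with a median of 0.72 (percentile 94.8). Fn1 was at 7.11 against 3.71 FPKM (0.78) and Ly6c2 at 3.75 against 4.48 (-0.21).

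The cord libraries held 595 features at least 2-fold higher and 219 at least 2-fold lower ipsilaterally, 73.1% of them higher. The authors' deposited table calls 645 features significantly higher and 221 significantly lower. Of the 2-fold features, 389 higher and 93 lower ones are also called in the authors' deposited table. A filter at 5 FPKM left 373 higher and 130 lower, and pseudocounts of 0.1 and 3 FPKM gave 964 and 264 higher and 481 and 81 lower.

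The nerve injury list had a median of 0.29 over 25 genes in cord (percentile 99.0), with 4 genes at least 2-fold higher. These were Sprr1a at 21.1 against 1.87 FPKM (2.94), Atf3 at 9.59 against 1.05 (2.37), Npy at 87.3 against 25.9 (1.72) and Gal at 33.8 against 10.3 (1.62). The list no longer stood apart without a filter on low values, with a median of 0.10 (percentile 84.1), or after the GC correction, with a median of 0.20 (percentile 97.4).

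Innate immune genes beyond the myeloid markers were also higher in ipsilateral cord. Interferon response genes had a median of 0.49 over 26 genes (percentile 100), 6 of them 2-fold higher, including Igtp at 5.29 against 1.0 FPKM (1.65) and Irf7, a regulator of the interferon response, at 5.01 against 0.97 (1.61). Complement genes had a median of 0.55 over 12 genes (percentile 99.7), 4 of them 2-fold higher, with C1qa at 80.3 against 14.0 FPKM (2.43). Antigen presentation genes had a median of 0.40 over 14 genes (percentile 99.4), with H2-DMa at 9.38 against 1.33 FPKM (2.15) and B2m at 133 against 65.2 (1.02). Reactive astrocyte genes had a median of 0.52 over 17 genes (percentile 99.7), with Cxcl10 at 2.23 against 0.047 FPKM (1.62) and Gfap, the astrocyte filament gene, at 881 against 469 (0.91). Without a filter on low values the complement list (median 0.17, percentile 87.4) and the antigen presentation list (median 0.12, percentile 76.3) no longer stood apart. The cytokine and chemokine list had a median of -0.17 over 15 genes (percentile 10.5), although Tgfb1 was at 4.83 against 0.34 FPKM (2.12).

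The medians of most neuronal and glial lists were near 0 in cord. The median was -0.01 over 37 potassium channel genes (percentile 37.3) and 0.04 over 30 sodium, calcium and HCN channel genes (percentile 63.3). The median was 0.03 for 17 dorsal horn excitatory neuron genes (percentile 57.1), -0.01 for 16 inhibitory neuron genes (percentile 47.3) and -0.02 for 8 motor neuron genes (percentile 39.2). Of the motor neuron genes, 2 were at least 2-fold higher, Prph at 8.0 against 3.14 FPKM (1.12) and Calca at 2.91 against 0.56 (1.32), and 5 were below 0. The authors' deposited table calls neither Prph nor Calca. Astrocyte genes had a median of -0.02 over 16 genes (percentile 42.2) and oligodendrocyte lineage genes 0.03 over 18 genes (percentile 52.2). Receptor genes for GABA, glycine and glutamate had a median of -0.21 over 33 genes (percentile 0.81), which became -0.16 (percentile 2.78) after the GC correction. Their lowest member was Gabra2, a GABA receptor subunit gene, at 10.1 against 41.5 FPKM (-1.93), 4.09-fold lower with an interval of 2.69 to 6.22 from the authors' deposited table. Proliferation genes had a median of 0.13 over 14 genes (percentile 67.4), with 6 below 0. The cyclin gene Ccna2, at 3.15 against 0.86 FPKM (1.16), was the 1 member at least 2-fold higher, while Birc5 was at 1.77 against 3.42 (-0.67). Over the 31 cord lists with a percentile, 9 stood above and 1 below, where lists of randomly drawn genes would put 1.55 outside. The limit given for the DRG lists holds here too.

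**Figure D2:**
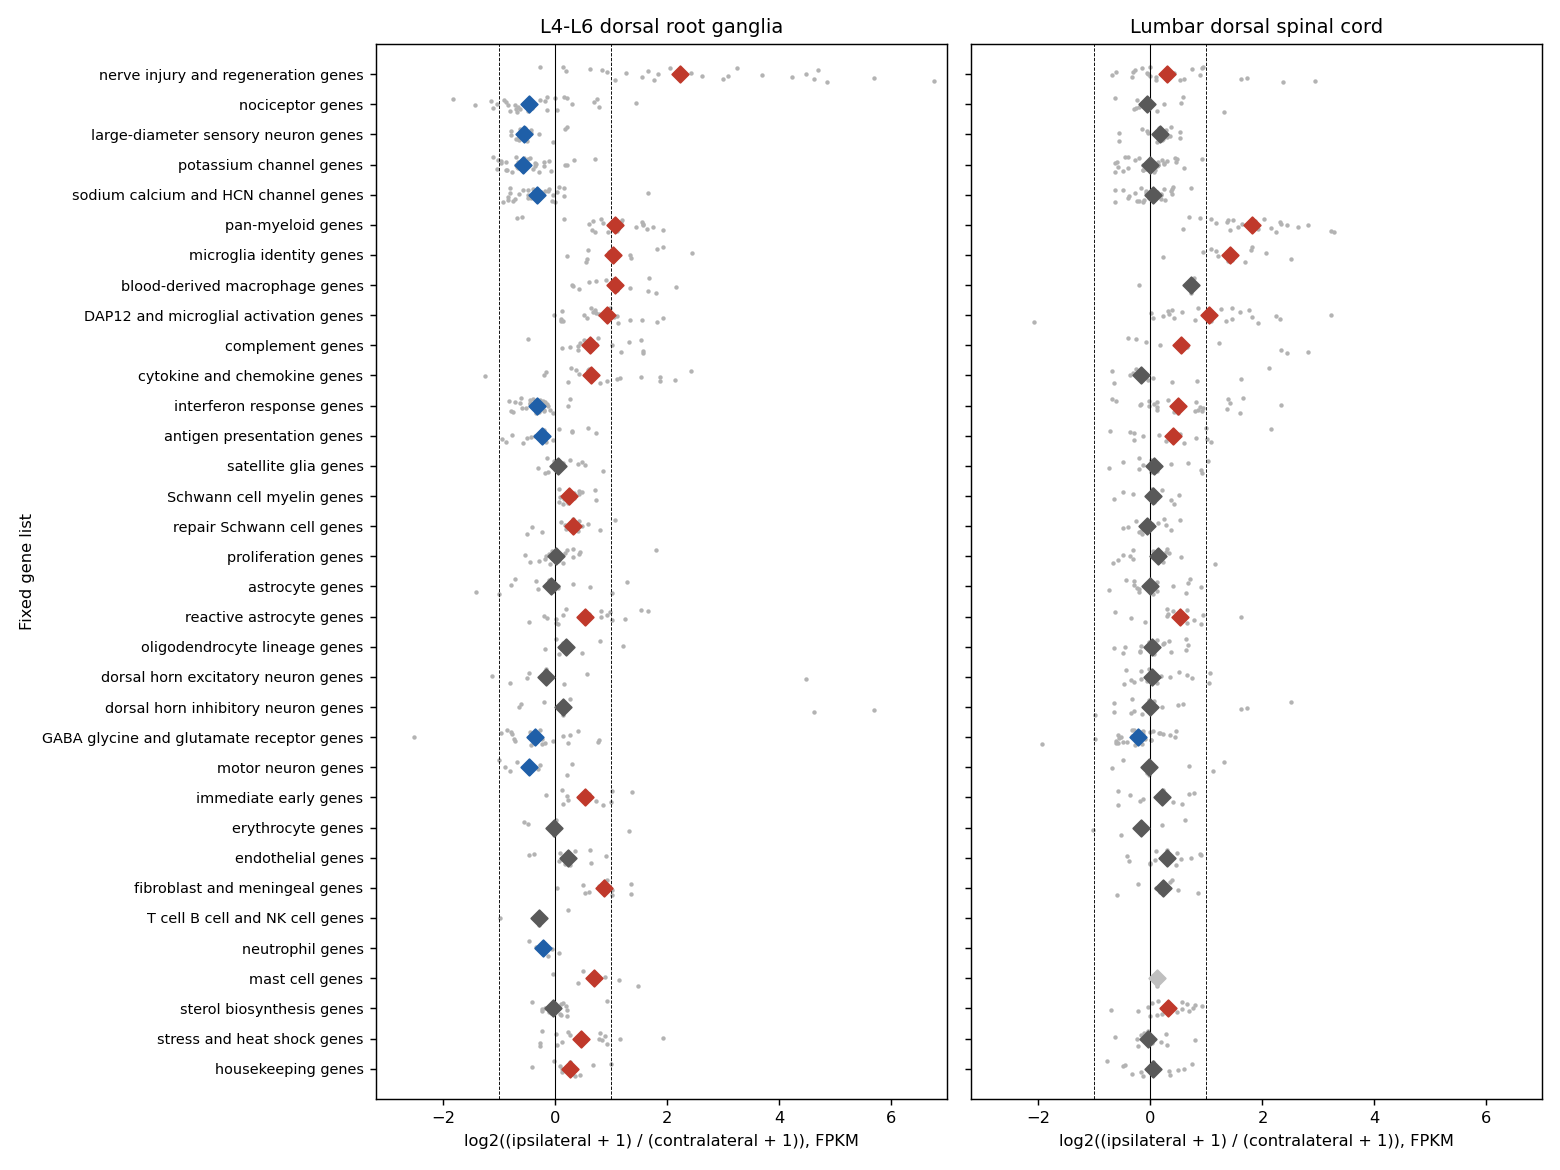
Median log2 ratio (diamonds) and single genes (grey points) of the fixed gene lists in DRG (left) and dorsal cord (right), on the scale log2((ipsilateral + 1) / (contralateral + 1)) in FPKM. Red diamonds stand above and blue ones below matched random lists, dark grey ones lie within and the pale one has too few genes; lists with too few genes in both tissues are not shown. The injury list lies at 2.23 in DRG and 0.29 in cord, and the pan-myeloid list at 1.06 and 1.81.

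More genes were at least 2-fold higher in both tissues than independent lists would share. Of 12229 genes measured in both, 55 were at least 2-fold higher in both, where independent lists of these sizes would share 10.4. Among them, 5 were small RNA features. Without such features, an alternative chosen after seeing the data, the count was 50 against 9.81. Of these 55, 20 belonged to the myeloid, microglia, complement or DAP12 lists and 4 to the injury list (Atf3, Gal, Npy and Sprr1a). Csf1r had log2 ratios of 1.92 in DRG and 1.81 in cord, and Fcrls 2.45 and 2.07. Outside these lists, Tnnc1, a troponin gene, had 2.40 and 2.52 and the annexin gene Anxa10 had 2.69 and 1.90. The number was 35 when the authors' calls in both of the authors' deposited tables were also required.

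The genes lower in both tissues numbered 4, where independent lists would share 0.77. These were the anchoring protein gene Akap5 (-2.05 in DRG and -1.65 in cord), the neuropeptide gene Cartpt (-1.35 and -1.69), 1700007G11Rik (-1.22 and -1.31) and Hmgb1-rs17 (-1.14 and -1.09). Only Akap5 and Cartpt are called in both of the authors' deposited tables. 1700007G11Rik and Hmgb1-rs17 were under 1 FPKM ipsilaterally in both tissues. In opposite directions, 9 genes were at least 2-fold higher in DRG and lower in cord, where independent lists would share 3.72, and 5 were lower in DRG and higher in cord, against 2.15. Of these, 5 and 3 were small RNA features, and without such features, an alternative chosen after seeing the data, the counts were 4 against 3.40 and 2 against 1.85. Across the 12229 genes, the log2 ratios of the tissues had a Pearson correlation of 0.078 and a Spearman correlation of 0.052. Genes are not independent replicates, so no p-value is given.

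The cord comparison carried a trend with GC content that DRG did not show to the same extent. In cord the Spearman correlation of the log2 ratio with transcript GC content was 0.30 across 12242 genes at 1 FPKM or more in both libraries, and the median log2 ratio went from -0.20 in the lowest of 10 equal GC classes to 0.21 in the highest. In DRG the correlation was -0.06 across 12181 such genes, and these medians were 0.08 and -0.02. Gabra2, with a GC content of 38.4%, lay in the lowest class. The median of that class in cord was -0.20 and its lower quartile -0.42, against -1.93 for Gabra2.

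**Figure D3:**
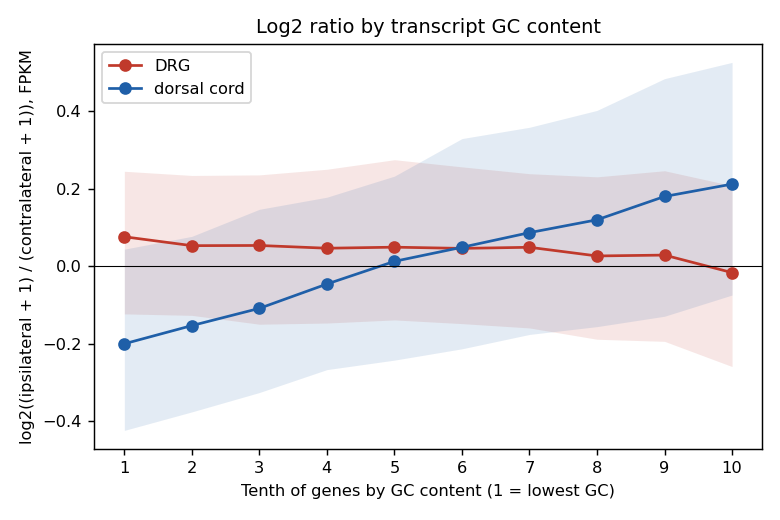
Median log2 ratio (points) and quartiles (shading) of genes at 1 FPKM or more in both libraries, in 10 equal classes of transcript GC content, in DRG (red) and dorsal cord (blue), in log2 of FPKM + 1. The cord medians climb from -0.20 to 0.21 with GC content while the DRG medians go from 0.08 to -0.02.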

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

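The tests of GC content and of blood for the myeloid genes, and the tests of motor neurons and GC content for the axotomy genes, were chosen after the results were seen, and so were the GC correction itself, the pan-neuronal comparison for lists other than potassium channels and the choice of Sncg.

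Interferon response genes stood apart in opposite directions, with a median log2 ratio of -0.33 in DRG and 0.49 in dorsal cord. Antigen presentation genes did the same, at -0.24 in DRG and 0.40 in cord, but in cord they no longer stood apart without a filter on low values (median 0.12, percentile 76.3). Among single genes, BC096441 had log2 ratios of 1.91 in DRG and -1.77 in cord, but the cord value rests on a library listed at 0 (2.42 FPKM contralaterally), which can be a failed estimate. Rpl34-ps1, a ribosomal pseudogene that can share reads with its parent gene, had log2 ratios of 3.80 in DRG and -4.37 in cord. For Rpl34-ps1 the authors' deposited tables call the cord difference but not the DRG one. None of these differences between tissues was tested, since each side of each tissue has 1 library.

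The myeloid genes of ipsilateral dorsal cord, with a pan-myeloid median of 1.81, were weighed against technical sources. After the GC correction the median was 1.77, which argues against the GC trend as the whole cause. Blood carried into the ipsilateral library would bring haemoglobin RNA, but Hba-a1, which has a near-identical copy, had a log2 ratio of -0.53 (123 against 179 FPKM). What stays open, as an untested hypothesis, is a response of microglia to the cut nerves, which could be more cells, more RNA of these genes per cell, or both. A difference in dissection between the sides also remains untested.

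The lower potassium channel genes of ipsilateral DRG could reflect a smaller share of neuronal RNA as other cells gain. A list of 30 pan-neuronal genes, 28 of them measured, had a median of -0.25, with 20 genes below 0, and the potassium channel median lay 0.33 below it. The 95% bootstrap interval over genes was 0.14 to 0.55, but genes are not independent replicates, and single pan-neuronal genes ranged from -0.82 to 0.50. Within these libraries the gap argues against an equally lower share of all neurons as the whole cause, though such a share may be part of it. A lower share of only some neuron types was not tested. The same difference was 0.30 (0.16 to 0.55) for the large-diameter list, but 0.22 (-0.11 to 0.54) for the nociceptor list and 0.08 (-0.10 to 0.35) for the sodium, calcium and HCN channel list, so for the latter lists a lower neuronal share stays open. After the GC correction the potassium channel list had a median of -0.61 and stayed at percentile 0, and a lower expression of these genes in the cut neurons remains a hypothesis.

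The axotomy genes Atf3, Sprr1a, Gal and Npy were higher in ipsilateral cord as well as in DRG. RNA of injured DRG in the cord library would bring other abundant DRG transcripts. This was weighed across 24 genes at 50 FPKM or more in ipsilateral DRG and under 0.5 FPKM in contralateral cord. Their median gain was 0.0027% of the DRG level and the highest 1.27%, against 2.45% for Sprr1a and 2.19% for Atf3. Gal gained 10.1% and Npy 16.4%, but these 2 genes were already at 10.3 and 25.9 FPKM in contralateral cord. All these shares come from separately normalised tables. Outside these 24, Sncg, already at 36.9 FPKM in contralateral cord, gained 2.78% and Prph 0.495%, so the argument rests on the median, while against the GC trend the corrected median of the 4 axotomy genes was 1.93. More motor neurons in the ipsilateral library stay open. Chat and Slc5a7 had a mean log2 ratio of -0.047 but were at 3.20 FPKM or less. Prph (1.12) and Calca (1.32) were higher in cord, though the authors' deposited table calls neither. Both were also abundant in ipsilateral DRG, at 982 and 227 FPKM, so they bear on DRG RNA as well. Injured motor neurons in an equal share of both libraries, a matching loss of cholinergic transcripts in them, RNA carried in axons, and expression by cord cells all stay open and untested.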

How the results depend on the processing

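The GC correction, the count without small RNA features and the count that also needs the authors' call were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. Of 82 comparisons of the 7 main results with an alternative, 56 stayed within the limit of 1.5 times (or the interval of the correlation) and 0 reversed. Removing the filter could not change the 2-fold counts. With a pseudocount of 1 FPKM, a gene under 1 FPKM on both sides cannot reach 2-fold. With a pseudocount of 0.1 FPKM, 679 genes were higher and 259 lower in DRG, 964 and 481 in cord, and 112 and 18 in both tissues. With 3 FPKM these counts were 204 and 44, 264 and 81, and 23 and 2. A filter at 5 FPKM gave 68 lower genes in DRG, 373 higher and 130 lower in cord, and 32 higher and 2 lower in both tissues. The calls of the authors' deposited tables gave 649 higher and 266 lower in DRG and 7 lower in both tissues. The fold and the authors' call together gave 63 lower in DRG, 389 higher and 93 lower in cord, and 35 higher and 2 lower in both tissues. Pseudocounts and filters act on low genes, and the joint rule is narrower, by construction. The cause of the other shifts was not tested. The GC correction moved the Spearman correlation between tissues to 0.0772. Median and upper-quartile rescaling shifted log2 ratios by less than 0.05 and kept every count within 1.5 times.

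Of 583 comparisons of list medians, 570 kept their side of the percentile limits, 7 lost it, 6 gained one and 0 reversed. Lists that gained a call were, in DRG, astrocyte genes at a filter of 5 FPKM (percentile 2.32), dorsal horn excitatory genes without a filter (0.89) and after the GC correction (2.05), and inhibitory genes at 5 FPKM (99.99). In cord they were erythrocyte genes at 5 FPKM (2.30) and endothelial genes at a pseudocount of 3 FPKM (98.2). Of 3304 comparisons of named genes, 3198 kept their side of 2-fold, 64 fell under it, 42 passed it and 0 reversed. The filter settings, the authors' test status and summed rows leave a gene's log2 ratio as it is. In those settings a named gene could not change side, so many of the 3198 agreements were fixed in advance. Summing rows of a symbol changed nothing because symbols are unique, which makes that setting uninformative. Depth limits genes at 1 to 3 FPKM most, where the standard error implied by the authors' deposited table was 0.44 in DRG and 0.57 in cord.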

Other observations

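Several cell type and stress lists not described so far were higher in ipsilateral DRG. Fibroblast and meningeal genes had a median of 0.88 over 14 genes (percentile 100), 4 of them 2-fold higher, with the matrix gene Lum at 44.1 against 16.8 FPKM (1.34) and Dcn at 494 against 245 (1.01). Mast cell genes had a median of 0.69 over 6 genes (percentile 99.8), with the protease genes Cma1 at 8.05 against 2.27 FPKM (1.47) and Mcpt4 at 11.7 against 4.75 (1.14). Immediate early genes had a median of 0.53 over 13 genes (percentile 99.96), with Btg2 at 6.86 against 2.04 FPKM (1.37) and Egr1 at 12.1 against 5.53 (1.0). Stress and heat shock genes had a median of 0.45 over 17 genes (percentile 100), led by Chac1 at 8.07 against 1.4 FPKM (1.92) and Trib3 at 2.77 against 0.70 (1.15), which both act in the integrated stress response. Endothelial genes (median 0.22, percentile 93.7), erythrocyte genes (-0.03, 28.5), sterol biosynthesis genes (-0.04, 21.4), astrocyte genes (-0.08, 9.93), oligodendrocyte lineage genes (0.19, 90.5), T, B and NK cell genes (-0.29, 8.0) and the dorsal horn excitatory (-0.17, 3.0) and inhibitory lists (0.14, 76.6) lay within the range of matched lists. The skeletal muscle list had 1 measured member, Acta1 at 32.2 against 25.9 FPKM, and the adipocyte list 2, Fabp4 at 13.6 against 5.76 and Cfd at 2.51 against 0.21.

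In ipsilateral cord, sterol biosynthesis genes had a median of 0.32 over 18 genes (percentile 99.6), with Nsdhl at 22.6 against 11.5 FPKM (0.92), and after the GC correction the median was 0.33 (percentile 99.9). The lipid carrier gene Apoe was at 1356 against 666 FPKM (1.02). Single genes of the dorsal horn lists differed both ways around list medians near 0. Penk was at 335 against 160 FPKM (1.06) and Tac2 at 105 against 50.1 (1.05), while Gad1, encoding a GABA-synthesising enzyme, was at 45.8 against 91.8 (-0.99). The transcription factor gene Gbx1 was at 6.74 against 0.36 FPKM (2.51). The remaining cord lists lay within the range of matched lists: nociceptor (median -0.07, percentile 26.8), large-diameter sensory neuron (0.16, 88.7), satellite glia (0.06, 59.7), Schwann cell myelin (0.05, 51.0), repair Schwann cell (-0.06, 30.6), immediate early (0.20, 83.0), erythrocyte (-0.16, 21.2), endothelial (0.29, 97.1), fibroblast and meningeal (0.23, 83.4), stress (-0.05, 32.7) and housekeeping genes (0.05, 57.1). The mast cell and skeletal muscle lists had 1 measured member each in cord, and the T, B and NK cell, neutrophil and adipocyte lists had 0.

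Small RNA features filled the extremes of the plain ranking. Judged by symbol, 9 of the 10 largest and 10 of the 10 smallest log2 ratios in DRG were microRNA or small nucleolar RNA features, and in cord 9 of 10 and 10 of 10. For example, Snord57 was listed at 0 contralaterally in both tissues and at 309 FPKM ipsilaterally in DRG and 4572 in cord. The remaining feature among the 10 largest in cord, AF357355, has the same deposited coordinates as Mir1188, so it may be a small RNA too. It was listed at 0 contralaterally and at 3481 FPKM ipsilaterally. In the authors' deposited tables the small RNA features at these extremes had q from 0.108 to 0.676. Among the features past 2-fold, 48 higher ones in DRG and 75 in cord were listed at 0 contralaterally, and 22 and 31 lower ones at 0 ipsilaterally.

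Among cord genes called significant in the authors' deposited table, the lowest included Hist3h2ba at 3.81 against 18 FPKM (-1.98), Rps27l at 2.73 against 16.5 (-2.23) and Cks2 at 0.35 against 5.38 (-2.24). Tpt1, an abundant transcript with many pseudogenes, was at 74.6 against 272 FPKM (-1.85). In DRG the lowest such genes included the interferon-induced GTPase gene Iigp1 at 6.35 against 29.6 FPKM (-2.06) and the matrix gene Itih3 at 0.34 against 4.70 (-2.09). In cord, 939 features were listed at 0 contralaterally alone and 387 ipsilaterally alone, although 1 read was worth less FPKM in the contralateral library.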
